A study of Mus musculus with 16 samples.

How the data were processed

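Single-nucleus RNA sequencing libraries of mouse lung were analysed, 16 in all, with 4 in each of 4 groups. SKG mice carry altered T cell selection, and fungal cell wall sugars trigger arthritis and lung inflammation in them. Per the series' design text, male animals of this strain were given zymosan once into the peritoneum (7.5 mg per 20 g) at 8 to 10 weeks of age. They were then injected 2 times a week with PBS, with methotrexate (MTX, 7.5 mg/kg) or with a TNFα inhibitor (TNFi, 100 µg/kg). Per the labels, the groups were ZyA_PBS (zymosan, then PBS; the positive control), ZyA_MTX, ZyA_TNFi and PBS (the negative control). The comparisons are called the disease (ZyA_PBS against PBS), MTX (ZyA_MTX against ZyA_PBS), TNFi (ZyA_TNFi against ZyA_PBS) and drug comparison (ZyA_MTX against ZyA_TNFi). The first 3 share the ZyA_PBS libraries, so overlaps of their calls were not interpreted. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples, which may be technical.

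Per the labels' protocols, lung was minced in a nuclei lysis buffer with protease and ribonuclease inhibitors, dissociated mechanically, strained and pelleted, and 10x Chromium libraries were made from the nuclei. The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, written by Cell Ranger 4.0.0 per the file headers, with the build mm10 per the submitters' processing notes. Each library lists 32285 genes. The annotation release and whether intronic reads were counted are not given in the sources used here. The barcodes had been filtered before deposit. The lowest UMI total of a barcode was 500 or 501 in 8 libraries. It lay between 47 and 455 in the others (all ZyA_PBS, ZyA_MTX replicates 2 to 4 and ZyA_TNFi replicate 4). The same calling of nuclei in all libraries is therefore doubtful, and compared shares of nuclei may reflect it. Replicates differed by more than counting noise in all 24 within-group pairs, with a chi-square per degree of freedom of 3.72 to 54.6.

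Nuclei with at least 200 genes detected and under 10% mitochondrial UMIs were kept (54053 of 59860 barcodes). Scrublet, run per library through scanpy 1.11.5 with an expected doublet rate of 6%, marked 829 of them (1.53%), which were left out, so 53224 nuclei were used. Counts were scaled per nucleus and log-transformed, and 3000 variable genes (detected in at least 50 nuclei), 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 gave 44 clusters (scanpy, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). A cluster took the name of the class whose fixed markers it held most, with at least 3 markers at 20 CPM or more and 2-fold or more above the other clusters. This gave 37 named clusters in 19 classes and 7 unnamed clusters. Names therefore mean AT2-like, AT1-like and so on, and the suffix is mostly left out below. The class written as macrophage/monocyte covers interstitial macrophages and monocytes.

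Genes were tested in 6 classes (AT2, AT1, fibroblast, endothelial, macrophage/monocyte and T). UMI counts were summed per library and class (pseudobulk), sums of fewer than 20 nuclei were left out (only the T sum of ZyA_PBS replicate 4, so that n = 3 there), and all libraries entered one edgeR 4.0.16 quasi-likelihood fit per class (R 4.3.3) with TMM scaling and filterByExpr at its minimum count of 10. Tests were two-sided, with Benjamini-Hochberg adjustment per class and comparison at 0.05, and every adjusted p of a gene below comes from this edgeR test. Expression is given as CPM of the TMM-scaled class sum, mean ± SD over libraries, and fold changes as log2 ± SE. Shares of nuclei were compared for 7 classes (the 6 above and B) by an exact two-sided permutation test of the mean percent per library. Its 70 assignments allow no p below 0.0286, and p was adjusted over the 7 classes. The log2 ratio of AT2 to AT1 nuclei (0.5 added to both counts) was tested the same way.

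Gene lists were tested against the other genes of a class with camera (limma 3.58.1, correlation between genes preset at 0.01), adjusted over the 63 class-by-list tests of a comparison, and again with the correlation estimated for each list. Lists with fewer than 5 tested members in a class were left out. The 21 lists covered the interferon response, antigen presentation, TNF and NF-kB targets, p53 targets, folate and nucleotide synthesis, cell cycle, immediate early and heat shock genes, amino acid and ER stress, mitochondrially encoded genes, extracellular matrix, surfactant and lipid synthesis, AT2 progenitor genes, the transitional alveolar state, epithelial acute phase, AT1 identity, alveolar fibroblast identity, capillary identity, endothelial activation, fibrosis-associated macrophages, Th17 and T cell activation. Lists, markers, tests and most alternatives were fixed before the data were examined.

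The genes named were also set by a rule. Per comparison and class it took up to 3 higher and 2 lower genes with the largest fold change among those past the threshold with an average log2 CPM of at least 5 and no overlap between the libraries of both groups, leaving out unnamed gene models, mitochondrial, ribosomal protein, haemoglobin and antigen receptor genes and markers of other classes. It added up to 4 members of the lists with the smallest p past the threshold. Some of these genes are left out of the report, among them most whose call was kept in 3 or fewer of the fits without 1 library, and where such a gene is named its limit is given. In the disease comparison and in both comparisons of ZyA_MTX it added, passed or not, Sftpc, Sftpb, Abca3, Lamp3, Etv5, Axin2, Krt8, Cdkn1a and Lcn2 in AT2, Ager and Hopx in AT1, and Col1a1 in fibroblasts. Chance puts all libraries of one group on one side of the other for 2.86% of genes (5.71% in T nuclei of ZyA_PBS). A few other members of the lists, chosen after their values were seen, are given as examples with their log2 fold change alone. Positions are from the GENCODE vM21 annotation (GRCm38), where all 145 named genes were found.

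For genes with 1 to 3 UMIs in a group, the ratio of their UMI sums, each divided by the group's UMI total for the class, is given with its 95% counting interval, and for 0 UMIs a bound against 3 counts over the group. Both cover counting error only. The edgeR step was tested on simulated AT2 counts with 200 genes changed. In the disease, MTX, TNFi and drug comparisons, it recovered 28.6%, 16.5%, 31.2% and 52% of 2-fold and 76.5%, 68.4%, 81.8% and 85.9% of 4-fold changes. Over 10727, 10662, 10677 and 10718 genes, 1.91%, 3.49%, 0.893% and 6.16% of calls were false. Rates in the real libraries were not tested.

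The alternatives were DESeq2 1.42.0, DESeq2's size factors within edgeR (RLE), no low-count filter, only the groups compared, depth (log10 UMIs of the class sum) as a covariate, the replicate number as a block, nuclei with at least 500 genes, doublets kept, Leiden resolution 2.0, an edgeR test of nuclei counts and each library left out in turn. A covariate for the share of UMIs in ribosomal protein genes was added after seeing the data, as was this or depth as a covariate together with an estimated correlation.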

Results

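Nuclei from lungs of SKG mice were profiled in 4 libraries for each group, namely PBS and, after zymosan (a yeast cell wall preparation), ZyA_PBS, ZyA_MTX and ZyA_TNFi. The series title names the question of whether methotrexate, an inhibitor of folate metabolism, harms alveolar epithelial cells under systemic inflammation. The deposited matrices held 13026 barcodes in PBS, 10796 in ZyA_PBS, 21198 in ZyA_MTX and 14840 in ZyA_TNFi, of which 12773, 7579, 18251 and 14621 entered the analysis. Median UMIs per barcode were 1770 to 2716 in PBS and 1789.5 to 2478 in ZyA_TNFi, but 175 to 1730 in ZyA_PBS and 357 to 1808 in ZyA_MTX. The shallowest library, ZyA_PBS replicate 4, kept 856 of its 4002 barcodes. Depth therefore differed between the groups compared. AT2 sums held 72736 to 956640 UMIs per library in ZyA_PBS and 370980 to 2852000 in the other groups.

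**Figure D1:**
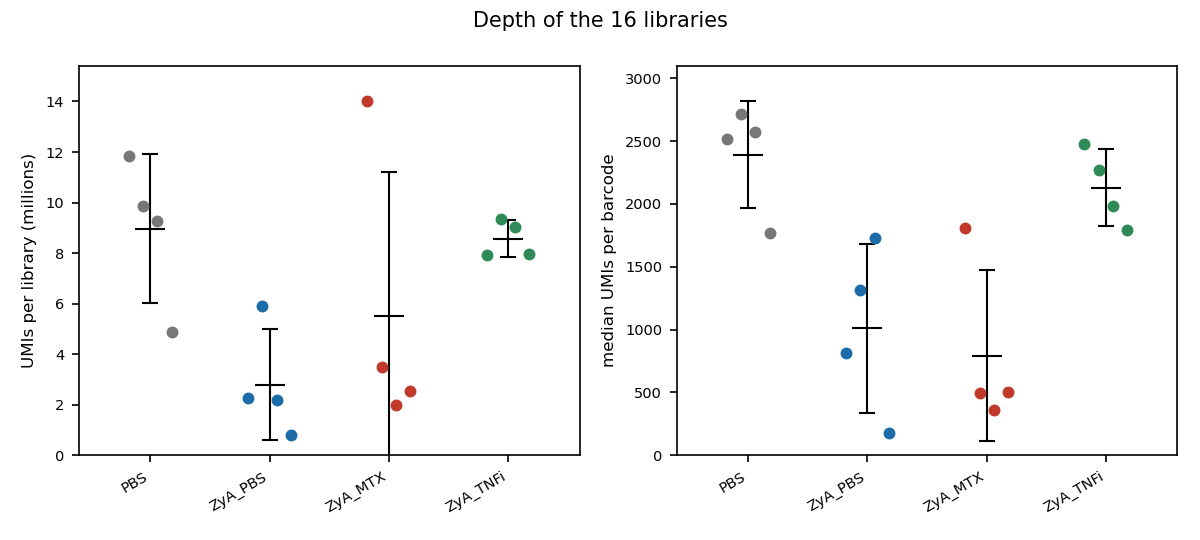
Total UMIs per library and median UMIs per barcode, 1 point per library, with the group mean and SD (n = 4; bars end at the axis). The ZyA_PBS and ZyA_MTX libraries spread from medians of 175 to 1808, while all PBS and ZyA_TNFi libraries lie at 1770 or above.

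The named clusters fell into 19 cell classes. AT2-like nuclei, the surfactant-making cells that also renew the alveolar epithelium, made up 22.8 ± 4.76% of nuclei in PBS, 13.03 ± 7.89% in ZyA_PBS, 19.0 ± 2.54% in ZyA_MTX and 22.6 ± 5.34% in ZyA_TNFi (SD, n = 4 libraries a group, as for all values below unless stated). AT1-like nuclei, the thin cells of gas exchange, stood at 7.95 ± 1.80%, 6.94 ± 2.85%, 4.72 ± 0.548% and 8.39 ± 3.25% in the same order. Macrophage/monocyte-like nuclei stood at 4.82 ± 1.68%, 8.53 ± 7.62%, 16.3 ± 4.69% and 3.87 ± 0.669%, and T-like nuclei at 5.19 ± 1.91%, 7.42 ± 7.38%, 13.9 ± 2.07% and 4.82 ± 1.26%. The 7 unnamed clusters held 0.95%, 5.15%, 5.77% and 2.61% of nuclei on average. Different clusters led a class in different groups. Their median UMIs (in brackets) differed, so these splits may follow depth, and calls may reflect the mix of nuclei. In AT2, cluster 0 (2497) held 86.5% in PBS and 84.5% in ZyA_TNFi, and cluster 2 (669) 56.2% in ZyA_PBS and 65.5% in ZyA_MTX. In AT1, cluster 5 (3589) held 93.8% in PBS, 84.0% in ZyA_TNFi and 54.2% in ZyA_PBS, and cluster 20 (768) 58.5% in ZyA_MTX. In endothelial nuclei, cluster 4 (1552) held 57.2% in PBS and 59.1% in ZyA_TNFi, and cluster 13 (479) 43.6% in ZyA_MTX and 30.3% in ZyA_PBS. In macrophage/monocyte nuclei, cluster 15 (1377.5) held 57.3% in PBS and 57.02% in ZyA_TNFi, and cluster 7 (756.5) 39.2% in ZyA_PBS and 54.7% in ZyA_MTX. In T nuclei, cluster 10 (1252) held 65.4% in PBS, 58.8% in ZyA_TNFi and 52.2% in ZyA_PBS, and cluster 6 (424) 66.5% in ZyA_MTX. Fibroblasts formed cluster 11 alone.

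**Figure D2:**
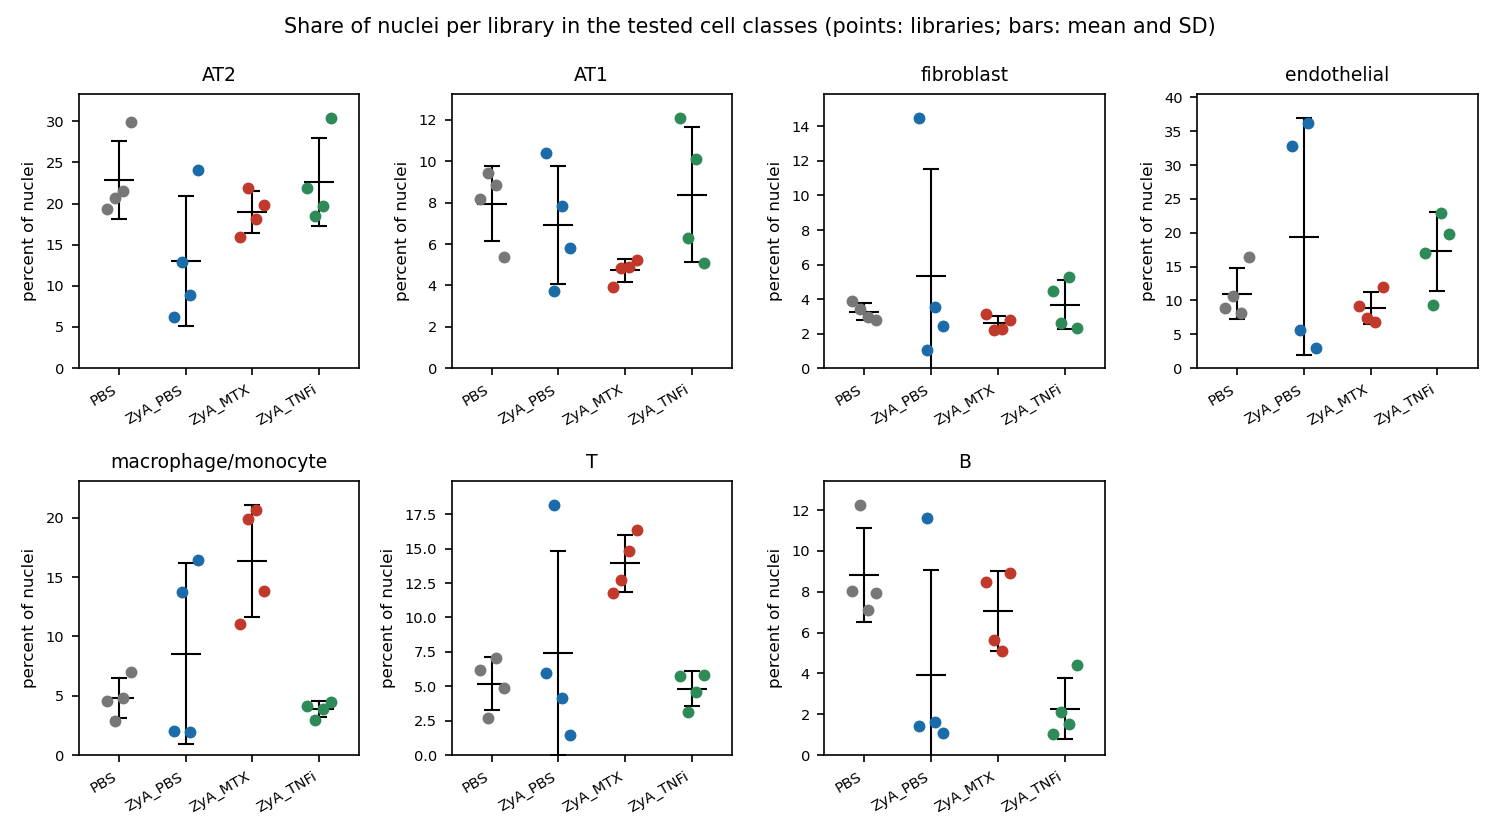
Percent of nuclei per library in the 7 tested classes, with the group mean and SD (n = 4). All 4 ZyA_MTX libraries lie above all 4 ZyA_TNFi libraries for macrophage/monocyte, T and B nuclei.

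The disease comparison, of ZyA_PBS with PBS, bears on zymosan without a drug, but the age and injection schedule of PBS are not given and may differ. In AT2-like nuclei, some interferon-induced genes were higher in ZyA_PBS. Gbp7, an interferon-induced GTPase, stood at 35.4 ± 26.7 CPM against 6.75 ± 3.43 CPM (log2 2.78 ± 0.46, adjusted p = 0.00715), but without ZyA_PBS replicate 2 (74.9 CPM) it did not pass (1.58, adjusted p = 0.446). Tap1, part of the transporter that loads peptides onto MHC class I, stood at 26.0 ± 28.9 against 10.2 ± 2.16 CPM with overlapping libraries (2.00 ± 0.41, adjusted p = 0.024). Its call rested on the same library (65.8 CPM, the others 0 to 27.4), without which log2 was 0.36 (adjusted p = 0.902). It was also lost without PBS replicate 1 (adjusted p = 0.0575) or 2 (adjusted p = 0.086). Oaz1, an antizyme that limits polyamine synthesis, fell from 60.6 ± 14.5 to 19.1 ± 7.71 CPM (-1.71 ± 0.35, adjusted p = 0.0215). The stress-induced transcription factor Klf6 fell from 50.3 ± 13.1 to 16.4 ± 5.92 CPM (-1.60 ± 0.34, adjusted p = 0.0296). Klf6 was lost without ZyA_PBS replicate 1, 2 or 3 or PBS replicate 1 or 2 (adjusted p = 0.0558 to 0.222), and Oaz1 without ZyA_PBS replicate 1 or 2 or PBS replicate 2 (adjusted p = 0.0555 to 0.245). The surfactant gene Sftpc did not pass, at 4747 ± 1452 against 7741 ± 1638 CPM (-0.70 ± 0.29, adjusted p = 0.419). Sftpb, Abca3, Lamp3, Etv5, Axin2, Krt8, Cdkn1a and Lcn2 did not pass either, with log2 fold changes of -0.40, -0.17, -0.17, 0.14, -0.50, -1.19, -0.39 and -0.01 and adjusted p of 0.411 or more. Nos2, the inducible nitric oxide synthase, passed (5.98 ± 0.96, adjusted p = 0.00715), but its 41 UMIs all came from ZyA_PBS replicate 2 (46.5 CPM, against 0 in the 3 other ZyA_PBS libraries). Against the 2 UMIs in PBS the ratio was 116 (95% counting interval 30.1 to 990), and without that library log2 was -1.98 (adjusted p = 0.925).

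In AT1-like nuclei a few identity genes were lower, though no gene passed with depth as a covariate. Spock2, a matrix proteoglycan gene, fell from 475 ± 59.7 to 212 ± 14.7 CPM (-1.19 ± 0.20, adjusted p = 0.00279), and Gprc5a, a receptor gene, from 1152 ± 135 to 620 ± 54.5 CPM (-0.88 ± 0.18, adjusted p = 0.0263). Of 21 AT1 identity genes, 3 fell (12 adjusted over the list alone) and all had a fold change below 0 (adjusted p = 6.49e-13 by camera, adjusted p = 0.0969 with an estimated correlation, written below as alone and estimated). Ager and Hopx did not pass (-0.77 and -0.64, adjusted p = 0.373 and 0.251). Immediate early and heat shock genes, a group induced within minutes of stress or handling, were lower by camera in all 6 classes. Nr4a1, an orphan nuclear receptor of this group, fell in AT1 nuclei from 60.3 ± 27.7 to 5.35 ± 4.35 CPM (-3.11 ± 0.51, adjusted p = 0.00248). It fell in macrophage/monocyte nuclei from 281 ± 87.6 to 36.5 ± 34.3 CPM (-3.07 ± 0.38, adjusted p = 0.000135) and in endothelial nuclei (-1.998 ± 0.42, adjusted p = 0.0271). Between 0 and 2 of the 10 to 17 members tested fell per class (2 to 10 alone), and adjusted p was 0.107 to 0.503 with an estimated correlation. In AT2 nuclei 1 member rose (adjusted alone). In fibroblasts, 4 of 14 alveolar fibroblast identity genes fell (6 alone; adjusted p = 0.000139, adjusted p = 0.31 estimated). Pparg, Tagln and Ager, markers of other classes, were lower there as well, and AT2 markers took 0.0358 ± 0.0219% of UMIs against 0.0837 ± 0.0301%. The identity genes included Mfap4, a microfibril protein gene (from 1319 ± 569 to 189 ± 136 CPM, -2.51 ± 0.54, adjusted p = 0.0272), Fgf10, a growth factor for the epithelium (-1.51 ± 0.34, adjusted p = 0.0177), and the amino acid transporter gene Slc7a10 (-1.32 ± 0.30, adjusted p = 0.0161). Lox, a collagen cross-linking enzyme, fell (-2.07 ± 0.46, adjusted p = 0.0161), and Col1a1 did not pass (59.1 ± 24.5 against 123 ± 31.4 CPM, -1.50 ± 0.43, adjusted p = 0.0539).

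Endothelial nuclei had less Akap12, a scaffold for kinases (219 ± 155 against 1273 ± 333 CPM, -2.31 ± 0.31, adjusted p = 0.000335), Snhg8 (-2.51) and Tnfrsf10b, a death receptor (-2.69 ± 0.48, adjusted p = 0.00531). They had more Nlrc5 and Ciita, the transactivators of MHC class I and class II genes (1.47 ± 0.29, adjusted p = 0.0146, and 2.08 ± 0.44, adjusted p = 0.0327, the latter kept in 3 of 8 fits without 1 library). Macrophage/monocyte nuclei had more Clmp, an adhesion molecule (555 ± 181 against 111 ± 22.3 CPM, 2.38 ± 0.24, adjusted p = 6.41e-06), Gbp7 (1.93 ± 0.35, adjusted p = 0.00908) and Myo10 (2.53). They had less Rel, an NF-kB subunit (-1.81 ± 0.34, adjusted p = 0.00908), and Stxbp6 (-2.60), and the airway marker Scgb1a1 was lower. Of 24 interferon response genes in AT2 nuclei, 2 rose (12 alone) and all lay above 0 (adjusted p = 5.91e-16, adjusted p = 0.275 estimated). This list passed in all 6 classes and antigen presentation in 4 (AT2, endothelial, macrophage/monocyte and T), with 0 to 2 members risen per class (0 to 12 alone, with 1 fallen in endothelial nuclei) and adjusted p of 0.275 to 0.686 with an estimated correlation. Without ZyA_PBS replicate 2, all these calls were lost (adjusted p = 0.113 to 0.99) except that of the interferon response in AT2 nuclei. Passing lists with lower members were the transitional alveolar state in AT1 nuclei (0 of 16 fell, 10 alone; median -1.05, adjusted p = 4.44e-11), p53 targets (endothelial and macrophage/monocyte), capillary identity, extracellular matrix (fibroblasts), surfactant and lipid synthesis (AT2) and T cell activation. Endothelial activation was higher (0 of 6 rose, 3 alone; adjusted p = 0.00114, adjusted p = 0.156 estimated). None of the 26 passing lists (11 higher, 15 lower, of 63) held with an estimated correlation, the smallest adjusted p being 0.0969.

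By edgeR's test, 35 genes in AT2 (19 higher, 16 lower of 10986), 33 in AT1 (1 and 32 of 6387), 108 in fibroblast (25 and 83 of 4641), 62 in endothelial (24 and 38 of 8224), 58 in macrophage/monocyte (25 and 33 of 6899) and 2 in T nuclei (1 and 1 of 5861; n = 3 in ZyA_PBS) passed. With depth as a covariate AT2 had 4, AT1 0, fibroblast 24, endothelial 32 and T 9, and macrophage/monocyte more. With RLE size factors the endothelial split was 19 and 48, and with DESeq2 25 and 67, and 5 and 9 in T nuclei. Leaving out 1 library gave 7 (ZyA_PBS replicate 2) to 71 genes (PBS replicate 4) in AT2, 4 (PBS replicate 2) to 164 (PBS replicate 4) in AT1 and 6 (ZyA_PBS replicate 1) to 246 (PBS replicate 4) in fibroblast. It gave 21 (PBS replicate 1) to 150 (PBS replicate 4) in endothelial, 26 (ZyA_PBS replicate 2) to 126 (PBS replicate 1) in macrophage/monocyte and 0 (PBS replicate 4) to 26 (ZyA_PBS replicate 1) in T nuclei. No share of nuclei passed (smallest possible exact p = 0.0286), so a difference is not excluded. AT2 and B nuclei (8.83 ± 2.30% in PBS, 3.95 ± 5.13% in ZyA_PBS) had the smallest p (exact permutation p = 0.114, adjusted p = 0.4), each lower in 3 of 4 ZyA_PBS libraries than in any PBS library. The log2 ratio of AT2 to AT1 nuclei was 0.82 ± 1.33 against 1.53 ± 0.63 (exact p = 0.4).

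The MTX comparison, of ZyA_MTX with ZyA_PBS, bears on what methotrexate added to zymosan. MHC genes, which present peptides to T cells, were higher in ZyA_MTX in several classes. In AT2 nuclei H2-Ab1 (class II) stood at 204 ± 44.6 against 57.4 ± 38.9 CPM (1.48 ± 0.28, adjusted p = 0.0124). H2-D1 (class I) stood at 940 ± 198 against 261 ± 177 CPM (1.68 ± 0.29, adjusted p = 0.0139). H2-T23, the folding enzyme gene Ppia and Oaz1 rose by 1.85, 1.76 and 1.72. The surfactant gene Sftpc stood at 11206 ± 4442 against 4747 ± 1452 CPM without passing (1.24 ± 0.30, adjusted p = 0.0732). The acute phase gene Lcn2, whose product binds bacterial siderophores, stood at 707 ± 316 against 103 ± 120 CPM (2.31 ± 0.69, adjusted p = 0.137). All 4 ZyA_MTX libraries lay above all ZyA_PBS libraries for both. Sftpb, Abca3, Lamp3, Etv5, Axin2, Krt8 and Cdkn1a did not pass (log2 0.47, 0.05, -0.05, 0.01, 0.38, 0.82 and 0.49, adjusted p of 0.183 or more). The AT2 progenitor list, of WNT, FGF and lineage regulators, did not pass in any comparison, and here 0 of 23 members changed (median 0.01, mean 0.08, camera direction down, adjusted p = 0.306). The surfactant and lipid synthesis list had a median of 0.14 and a mean of 0.42 (0 of 22 rose, 8 alone; adjusted p = 0.000186, adjusted p = 0.442 estimated).

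Antigen presentation passed in all 6 classes. In AT2 nuclei 2 of 16 members rose (9 alone; adjusted p = 5.09e-19, adjusted p = 0.102 estimated). The counts were 3 of 13 (11) in AT1, and in fibroblasts 7 of 11 (10), in endothelial nuclei 12 of 16 (13), and in macrophage/monocyte and T nuclei 0 of 16 (7) and 0 of 14 (2). Their adjusted p was 0.102 to 0.32 with an estimated correlation. In AT1 nuclei H2-D1 rose (710 ± 166 against 141 ± 106 CPM, 2.16 ± 0.37, adjusted p = 0.00979), as did the immunoproteasome gene Psmb8 (2.63), the ferritin gene Fth1 (2.70), Pcbp1 (2.67), Gabarap (2.53) and, with overlapping libraries, the interferon-induced Bst2 (2.40) and Ifit3 (1.55). Cdh13, an atypical cadherin, fell there (166 ± 71.3 against 572 ± 267 CPM, -1.83 ± 0.27, adjusted p = 0.00155), as did Sema5a (-1.85). Of the markers of other classes, Cxcl15, Sftpa1, Hbb-bs and Xbp1 were higher in AT1 nuclei and Csf1r lower. Ager stood at 1525 ± 613 against 655 ± 275 CPM (1.26 ± 0.37, adjusted p = 0.069) and Hopx at 0.37 (adjusted p = 0.445). In fibroblasts Col1a1, the main fibrillar collagen gene, rose from 59.1 ± 24.5 to 151 ± 43.5 CPM (1.80 ± 0.45, adjusted p = 0.0179), as did H2-Eb1 (3.04 ± 0.54, adjusted p = 0.00155), H2-Aa (3.21), H2-D1 (2.16), B2m (1.61) and the myeloid lysozyme gene Lyz2 (3.83, kept in 3 of 8 fits without 1 library). Extracellular matrix passed in fibroblasts, with 2 of 15 members risen (5 alone; adjusted p = 0.00151, adjusted p = 0.312 estimated). In endothelial nuclei H2-DMa rose from 13.4 ± 10.1 to 96.5 ± 17.97 CPM (2.57 ± 0.37, adjusted p = 0.000157). Irf7, a transcription factor of the interferon response, rose from 5.80 ± 5.50 to 61.1 ± 12.4 CPM (2.92 ± 0.47, adjusted p = 0.000454), as did Bst2 (2.05) and H2-DMb1 (1.96). Lcn2, Slpi and Retnla, secretory products of airway and AT2 cells, also rose in endothelial nuclei by 5.28, 4.82 and 4.66, where 15 markers of other classes were higher.

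Interferon response genes passed in 5 classes, with 0 to 10 members risen (0 to 12 alone; adjusted p of 0.202 to 0.743 with an estimated correlation), among them 10 of 27 in endothelial and 5 of 20 in AT1 nuclei. Epithelial acute phase genes passed in AT2 (0 of 13 rose, 6 alone; median 1.21, adjusted p = 5.57e-08, adjusted p = 0.202 estimated). TNF and NF-kB targets passed in AT2 (0 of 22, 4), AT1 (0 of 11, 3) and macrophage/monocyte nuclei (0 of 22, 0). So did amino acid and ER stress genes in fibroblasts (3 of 9, 6 alone) and endothelial nuclei (6 of 12, 8), capillary identity in endothelial nuclei (5 of 16, 6) and fibrosis-associated macrophage genes (0 of 19, 2). The transitional alveolar state, a set of keratin and stress genes seen when AT2 cells turn into AT1 cells, passed in AT2 (0 of 19, 0) and AT1 (0 of 16, 4; median 1.13, adjusted p = 0.000414, adjusted p = 0.442 estimated). In AT1 nuclei it turned lower (adjusted p = 0.018) with the ribosomal protein share as a covariate. Mitochondrially encoded genes were lower in AT2 nuclei (0 of 11 fell, median -0.41, adjusted p = 0.0194). No list of the 25 that passed (24 higher, 1 lower) held with an estimated correlation, the smallest adjusted p being 0.102. The ribosomal covariate gave 8 higher and 9 lower lists. Folate and nucleotide synthesis, the pathway methotrexate blocks, and Th17 passed in no class in any comparison. Here 0 of 22 folate and nucleotide synthesis genes changed in AT2 nuclei (median 0.34, adjusted p = 0.786) and 0 of 9 Th17 genes in T nuclei (1 fell alone; median 0.12, mean 0.14, camera direction down, adjusted p = 0.403).

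Ribosomal protein genes moved with these groups. Their share of UMIs was 0.664 ± 0.176% in ZyA_MTX against 0.338 ± 0.0580% in ZyA_PBS in AT2 nuclei and 0.934 ± 0.248% against 0.390 ± 0.135% in endothelial nuclei, and every ZyA_MTX library lay above every ZyA_PBS library in all 6 classes. Of the tested ribosomal protein genes, 11 of 87 rose in AT2, 46 of 77 in AT1, 43 of 62 in fibroblast and 71 of 86 in endothelial nuclei. AT2 marker genes took 0.248 ± 0.122% of UMIs in endothelial nuclei of ZyA_MTX against 0.0820 ± 0.0585% in ZyA_PBS, and 0.222 ± 0.104% against 0.0385 ± 0.0289% in T nuclei. They were also higher in AT1 (0.129 ± 0.0458% against 0.0427 ± 0.0335%), fibroblast (0.120 ± 0.0807% against 0.0358 ± 0.0219%) and macrophage/monocyte nuclei (0.139 ± 0.0569% against 0.0310 ± 0.0280%). In fibroblasts 4 markers of other classes were higher (Hba-a1, Hba-a2, Sftpa1 and Ager).

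**Figure D3:**
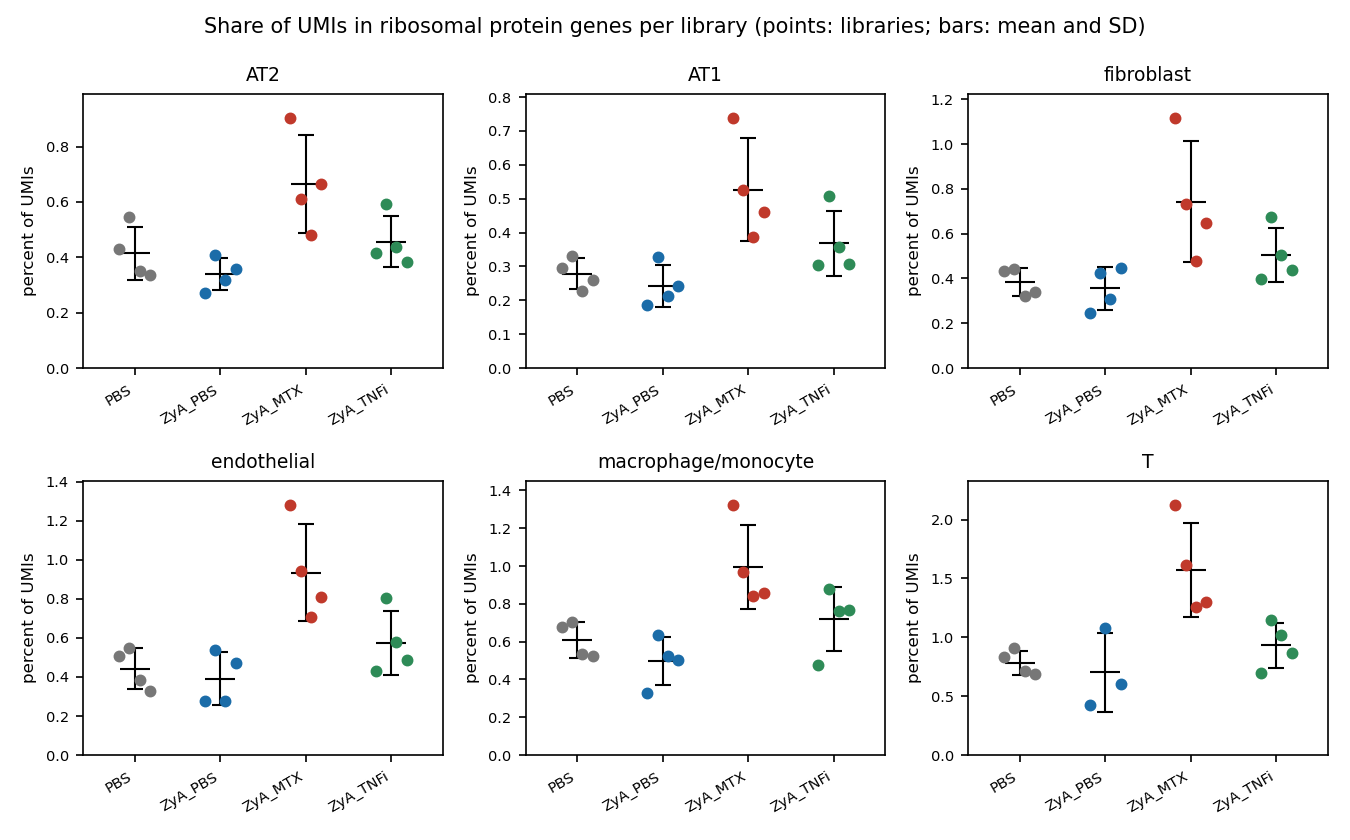
Percent of UMIs in ribosomal protein genes per library and class, with the group mean and SD (n = 4, and n = 3 for T nuclei of ZyA_PBS). In each class the 4 ZyA_MTX libraries lie above the ZyA_PBS libraries.

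The edgeR test passed 43 genes in AT2 (29 higher, 14 lower), 263 in AT1 (208 and 55), 197 in fibroblast (172 and 25), 984 in endothelial (735 and 249) and 11 in T nuclei (9 and 2). It passed 0 of 6899 in macrophage/monocyte nuclei, where 797 had an unadjusted p below 0.05 and DESeq2 called 83. In T nuclei Oaz1 (2.35) and the plasma cell marker Igha rose and Zbtb20 (-0.95) fell. With RLE size factors, which moved the median fold change of all genes by 0.15 in endothelial and 0.10 in fibroblast nuclei, the splits were 267 and 23 in AT1 and 992 and 152 in endothelial nuclei. With DESeq2 they were 670 and 106 in endothelial and 41 and 24 in T nuclei. With the ribosomal protein share as a covariate, chosen after seeing the data, 0 genes passed in AT2, AT1, fibroblast and T nuclei and 1 in endothelial nuclei, and none of the 39 genes of the rule that had passed kept its call. Leaving out 1 library gave 9 (ZyA_PBS replicate 3) to 121 genes (ZyA_PBS replicate 2) in AT2, 3 (ZyA_PBS replicate 1) to 316 (ZyA_PBS replicate 2) in AT1 and 0 (ZyA_PBS replicate 1) to 342 (ZyA_PBS replicate 2) in fibroblast. It gave 190 (ZyA_MTX replicate 1) to 1138 (ZyA_PBS replicate 4) in endothelial, 0 (ZyA_PBS replicate 3) to 170 (ZyA_PBS replicate 2) in macrophage/monocyte and 1 (ZyA_MTX replicate 1) to 300 (ZyA_PBS replicate 2) in T nuclei. No share of nuclei passed (smallest exact permutation p = 0.143, adjusted p = 0.32, for macrophage/monocyte and T nuclei, 16.3 against 8.53% and 13.9 against 7.42%). The log2 ratio of AT2 to AT1 nuclei was 2.00 ± 0.12 against 0.82 ± 1.33 (exact p = 0.143). Among nuclei with at least 500 genes it differed by 1.83, at the smallest possible exact p = 0.0286.

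**Figure D4:**
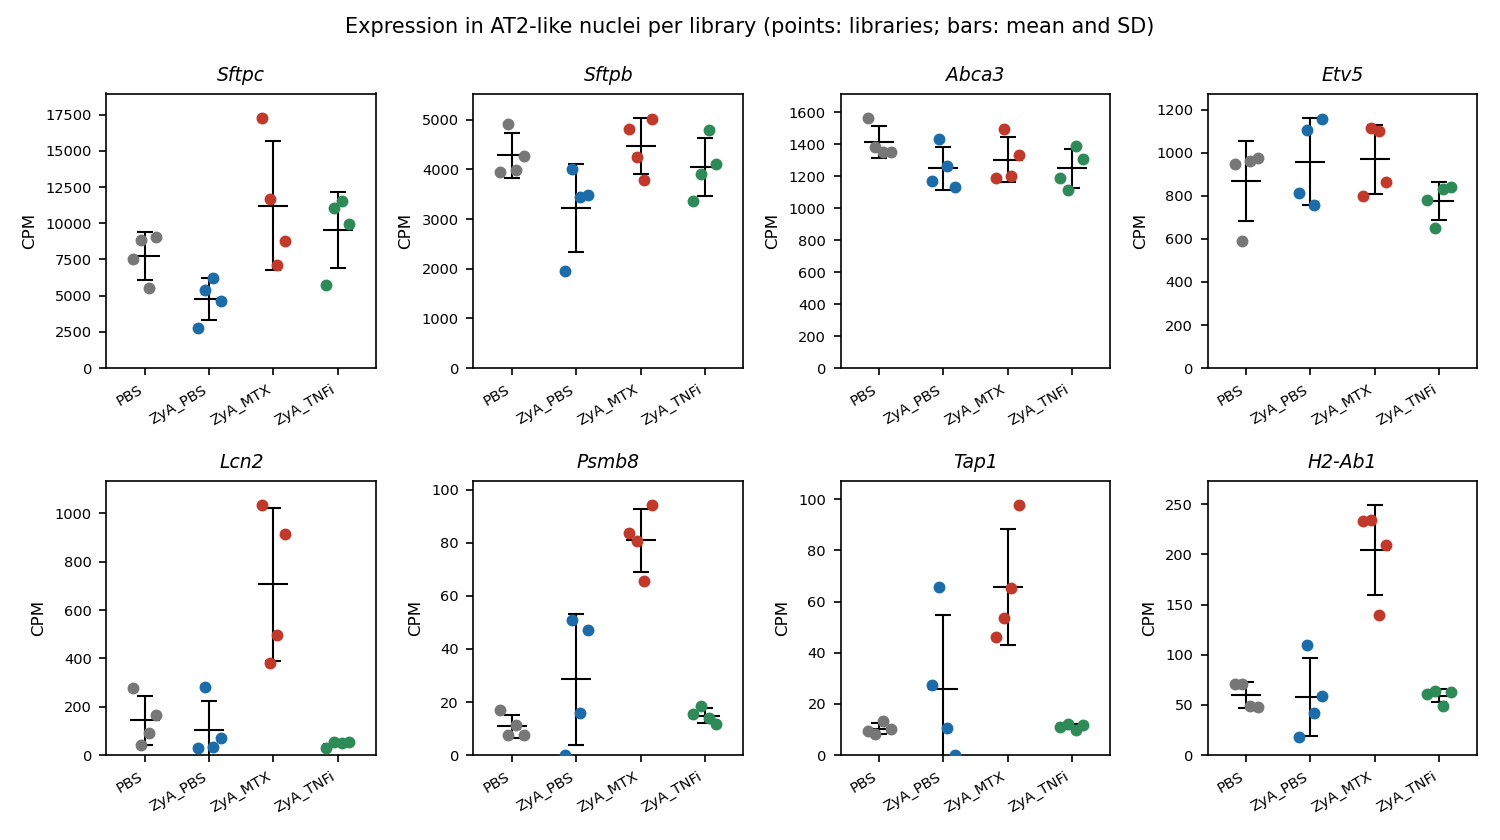
CPM in AT2 nuclei per library for Sftpc, Sftpb, Abca3, Etv5, Lcn2, Psmb8, Tap1 and H2-Ab1, with the group mean and SD (n = 4). For H2-Ab1 the ZyA_MTX mean is 204 and the ZyA_TNFi mean 59.2, and for Sftpc the groups of the drug comparison overlap.

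The TNFi comparison, of ZyA_TNFi with ZyA_PBS, bears on what the TNFα inhibitor changed under zymosan. In AT2 nuclei some interferon-induced genes were lower in ZyA_TNFi. Gbp7 stood at 9.38 ± 1.58 against 35.4 ± 26.7 CPM (-2.37 ± 0.44, adjusted p = 0.0165), and Tap1 and Gbp3, with overlapping libraries, fell by 1.87 and 3.82. Without ZyA_PBS replicate 2, Gbp7, Tap1 and Gbp3 did not pass (-1.16, -0.23 and -3.06, adjusted p = 0.557, 0.946 and 0.413). Tap1 was also lost without ZyA_PBS replicate 1 or ZyA_TNFi replicate 2, 3 or 4 (adjusted p = 0.0518 to 0.0831). Gbp3 was lost without ZyA_TNFi replicate 2, 3 or 4 (adjusted p = 0.0597 to 0.0674), and Gbp7 without ZyA_TNFi replicate 3 or 4 (adjusted p = 0.0605 and 0.065). All 24 interferon response genes had a fold change below 0 and 2 fell (11 alone; adjusted p = 2.19e-10, adjusted p = 0.585 estimated). Without ZyA_PBS replicate 2 this list did not pass (adjusted p = 0.229). Nos2 passed (-6.75 ± 1.02, adjusted p = 0.00984) on the 41 UMIs of that library, 246-fold above the 1 UMI in ZyA_TNFi (41.8 to 9965), and its log2 was 1.21 without it (adjusted p = 0.961). Tmtc4, a membrane protein gene of the ER, rose from 20.0 ± 13.6 to 65.6 ± 6.18 CPM (2.44 ± 0.45, adjusted p = 0.0157), with Oaz1 (1.80). In AT1 nuclei Btg2, an antiproliferative gene among the p53 targets, rose from 104 ± 41.2 to 280 ± 78.3 CPM (1.66 ± 0.27, adjusted p = 0.00271), as did Id3 (2.20 ± 0.40, adjusted p = 0.00389), Pcbp1 (2.71) and Tmem126a (2.13). Adamtsl3 and Tmem117 fell by 1.98 and 1.77, and the mesothelial marker Gpm6a was lower.

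In fibroblasts Atp8b1, a lipid flippase, fell from 217 ± 114 to 41.0 ± 18.4 CPM (-2.56 ± 0.37, adjusted p = 0.000202), and Colq by 2.11. Slc7a10 rose from 227 ± 68.9 to 513 ± 101 CPM (1.19 ± 0.30, adjusted p = 0.0346), as did Abhd14b (2.99) and, with overlapping libraries, the chaperone Hsp90b1 (1.56). Alveolar fibroblast identity passed (1 of 14 rose, 5 alone; adjusted p = 0.00439, adjusted p = 0.585 estimated). The AT2 and AT1 markers Sftpb and Ager were higher there as well, and AT2 markers took 0.103 ± 0.0473% of UMIs against 0.0358 ± 0.0219%. They were also higher in macrophage/monocyte (0.116 ± 0.0476% against 0.0310 ± 0.0280%) and T nuclei (0.126 ± 0.05996% against 0.0385 ± 0.0289%). In endothelial nuclei Ramp2, a co-receptor for adrenomedullin, rose from 239 ± 167 to 1891 ± 624 CPM (2.74 ± 0.43, adjusted p = 0.00363), as did Ppib (2.71), Dynlt1c (2.74), H2-D1 (2.04 ± 0.37, adjusted p = 0.00539), Bst2 (1.47) and the markers Lpl and Xbp1 of other classes. Mthfd1l, a mitochondrial folate enzyme, fell from 82.5 ± 28.3 to 26.4 ± 4.80 CPM (-1.74 ± 0.32, adjusted p = 0.00372). Amino acid and ER stress genes passed in endothelial nuclei (7 of 12 rose, 8 alone; adjusted p = 0.000241, adjusted p = 0.585 estimated) and fibroblasts (2 of 9, 5; adjusted p = 2.19e-05, adjusted p = 0.469 estimated). Antigen presentation was higher in endothelial (6 of 16, 8) but lower in AT2 nuclei (1 of 16 fell, 6 alone), both with an adjusted p of 0.755 with an estimated correlation. The AT2 call was lost without ZyA_PBS replicate 2 (adjusted p = 0.229). In macrophage/monocyte nuclei Pdcd1lg2, a ligand of the T cell receptor PD-1, fell from 117 ± 37.2 to 14.2 ± 8.83 CPM (-3.32 ± 0.72, adjusted p = 0.045, kept in 7 of 16 settings and 2 of 8 fits without 1 library), as did the proton channel gene Hvcn1 (-3.06) and, with overlapping libraries, the proliferation marker Mki67 (-3.61 ± 0.75, adjusted p = 0.0207).

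TNF and NF-kB targets were lower in T (0 of 16 fell, 7 alone; median -0.73, adjusted p = 0.000241), fibroblast (0 of 11, 0) and macrophage/monocyte nuclei (0 of 22, 6; median -0.64, adjusted p = 0.00439), with adjusted p of 0.585 to 0.742 with an estimated correlation. None of these calls held without ZyA_PBS replicate 2 (adjusted p = 0.228 to 0.968). Cell cycle genes were lower in AT2 (0 of 19 fell, 0 alone; adjusted p = 0.0241) and T nuclei (0 of 7, 2; adjusted p = 0.0495), with adjusted p of 0.773 and 0.585 with an estimated correlation. None of the 17 passing lists (8 higher, 9 lower) held with an estimated correlation (smallest adjusted p = 0.469). The split moved with the setting, to 4 higher and 16 lower with the ribosomal protein share as a covariate, 3 and 9 with depth and 12 and 2 without ZyA_PBS replicate 2. The edgeR test passed 49 genes in AT2 (22 higher, 27 lower), 189 in AT1 (90 and 99), 86 in fibroblast (59 and 27), 621 in endothelial (229 of them lower), 44 in macrophage/monocyte (10 and 34) and 4 in T nuclei (1 and 3). With RLE size factors the splits were 136 and 75 in AT1, 77 and 17 in fibroblast and 606 and 161 in endothelial nuclei, where all genes moved by a median of 0.13. With DESeq2 they were 44 and 99 in AT2, 298 and 91 in endothelial and 1 and 18 in T nuclei. Leaving out 1 library gave 0 (ZyA_PBS replicate 2) to 96 genes (ZyA_TNFi replicate 1) in AT2, 34 (ZyA_PBS replicate 1) to 286 (ZyA_PBS replicate 4) in AT1 and 2 (ZyA_PBS replicate 1) to 103 (ZyA_PBS replicate 2) in fibroblast. It gave 35 (ZyA_PBS replicate 1) to 738 (ZyA_TNFi replicate 1) in endothelial, 6 (ZyA_PBS replicate 2) to 114 (ZyA_PBS replicate 4) in macrophage/monocyte and 0 (ZyA_TNFi replicates 2, 3 and 4) to 16 (ZyA_PBS replicate 3) in T nuclei. With the ribosomal protein share as a covariate 16, 11, 4, 5 and 12 genes passed in AT2, AT1, fibroblast, endothelial and T nuclei. No share passed (smallest exact permutation p = 0.114, adjusted p = 0.8, AT2, 22.6 against 13.03%), and the log2 ratio of AT2 to AT1 nuclei was 1.49 ± 0.78 against 0.82 ± 1.33 (exact p = 0.429).

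The drug comparison, of ZyA_MTX with ZyA_TNFi, sets the treated groups side by side, and 3 of 4 ZyA_MTX libraries were shallow (medians of 357 to 506 UMIs, against 1789.5 to 2478). The interferon response and antigen presentation lists were higher in ZyA_MTX by camera in all 6 classes. With an estimated correlation the interferon response held in 4 of them (AT2, AT1, fibroblast and endothelial) and antigen presentation in 4 (AT2, AT1, fibroblast and T), but none of these held with the ribosomal protein share as a covariate as well. In AT2 nuclei Psmb8, an immunoproteasome subunit, stood at 81.0 ± 11.8 against 14.9 ± 2.77 CPM (2.46 ± 0.28, adjusted p = 1.11e-05), and Tap1 at 65.6 ± 22.7 against 11.1 ± 1.03 CPM (2.499 ± 0.33, adjusted p = 6.58e-05). H2-Ab1 stood at 204 ± 44.6 against 59.2 ± 6.67 CPM (1.81 ± 0.23, adjusted p = 4.61e-05), and the interferon-inducible GTPase gene Iigp1 at 662 ± 285 against 6.29 ± 6.58 CPM (6.75 ± 1.21, adjusted p = 0.00857). Of the lists, 15 of 16 antigen presentation genes rose in AT2 nuclei (16 alone; adjusted p = 4.1e-46, adjusted p = 0.00762 estimated). In AT2 nuclei 4 markers of other classes were higher too, the myeloid C1qa, C1qb and Ly6c2 and the fibroblast gene Slit2, so RNA of other cells is not excluded. Of the interferon response genes 20 of 24 rose (23; adjusted p = 1.31e-39, adjusted p = 0.0204 estimated). The neutrophil chemokine gene Cxcl1 rose (35.9 ± 11.8 against 3.49 ± 1.55 CPM, 3.42 ± 0.46, adjusted p = 9.11e-05). So did Lcn2 (707 ± 316 against 47.5 ± 11.9 CPM, 3.90 ± 0.67, adjusted p = 0.00643) and Tnfaip2, a gene induced by TNF (4.69 ± 0.97, adjusted p = 0.0196). Epithelial acute phase genes rose (8 of 13, 10 alone; adjusted p = 1.54e-15, adjusted p = 0.033 estimated). TNF and NF-kB targets rose too (8 of 22, 12; adjusted p = 1.21e-13, adjusted p = 0.0268 estimated). Gabre, a GABA receptor subunit, and Rarb, a retinoic acid receptor, fell (-1.22 ± 0.26, adjusted p = 0.00643, and -1.21 ± 0.29, adjusted p = 0.0158). The surfactant gene Sftpc stood at 11206 ± 4442 against 9562 ± 2620 CPM (0.23 ± 0.29, adjusted p = 0.841). Sftpb, Abca3, Lamp3, Etv5, Axin2, Krt8 and Cdkn1a did not pass (0.14, 0.06, 0.18, 0.32, -0.46, 0.42 and 0.30, adjusted p of 0.442 or more). In the AT2 progenitor list 1 of 23 members, the adhesion receptor gene Cd44, rose (0.83; median -0.06, adjusted p = 0.63). The transitional alveolar state passed with 3 of 19 members risen, namely Anxa1, Itgb6 and Tnip3 (1.98, 2.12 and 2.57; 6 alone; adjusted p = 8.66e-05, adjusted p = 0.288 estimated).

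In AT1 nuclei Oasl2 and Ifit2, interferon-induced antiviral genes, stood at 82.1 ± 20.5 against 4.21 ± 2.61 CPM (3.93 ± 0.56, adjusted p = 0.000561) and 65.1 ± 6.46 against 13.98 ± 5.99 CPM (2.27 ± 0.33, adjusted p = 0.000554). Psmb8, Xaf1, H2-Aa, H2-Ab1 and Ly6e rose by 2.19, 1.83, 2.76, 2.38 and 2.30 (the last 3 kept in 3, 1 and 3 of 8 fits without 1 library), Ppm1d fell by 1.95, and Ager and Hopx did not pass (0.46, adjusted p = 0.698, and -0.36, adjusted p = 0.635). AT2 markers took 0.129 ± 0.0458% of AT1 UMIs against 0.0750 ± 0.0518%. The AT1 level relative to the whole library was 1.63 and 1.52 times that of AT2 markers for H2-Aa and H2-Ab1, below the airway gene Scgb1a1 (2.44) as was Nlrc5, and 3.32, 2.96, 2.72 and 2.60 times for B2m, H2-D1, Psmb9 and Psmb8, above it. Of 20 interferon response genes 8 rose there (17 alone; adjusted p = 1.55e-30, adjusted p = 0.00927 estimated). Of 13 antigen presentation genes 7 rose (12; adjusted p = 4.5e-22, adjusted p = 0.023 estimated). In fibroblasts H2-Eb1 rose (183 ± 28.3 against 28.2 ± 3.42 CPM, 2.65 ± 0.40, adjusted p = 0.000188), with H2-Aa (2.66), Oasl2 (2.38), B2m (1.32) and Gbp5 (3.15). The fibroblast level relative to the whole library was 2.12, 2.18, 3.21 and 2.85 times that of AT2 markers for H2-Aa, H2-Ab1, H2-Eb1 and Nlrc5, below Scgb1a1 (3.32), and 5.44 times for B2m, above it, so free RNA is not excluded in either class. Cxcl10, an interferon-induced chemokine, had 1 UMI in ZyA_TNFi and was 175-fold higher in ZyA_MTX (30.7 to 6967), a call kept in 6 of 16 settings and 1 of 8 fits without 1 library. Col1a1 did not pass (151 ± 43.5 against 71.8 ± 36.7 CPM, 1.20 ± 0.35, adjusted p = 0.0887). Antigen presentation (5 of 11 rose, 10 alone; adjusted p = 0.0164 estimated) and the interferon response (2 of 16, 10; adjusted p = 0.0466 estimated) held in fibroblasts. The extracellular matrix list did not (0 of 15, 5; adjusted p = 0.000358, adjusted p = 0.173 estimated). In endothelial nuclei Irf7 rose from 17.2 ± 4.60 to 61.1 ± 12.4 CPM (1.70 ± 0.33, adjusted p = 0.013), with Xaf1 (1.26) and H2-DMa (1.33). There 7 of 27 interferon response genes rose (19 alone; adjusted p = 2.54e-32, adjusted p = 0.0194 estimated). Antigen presentation did not hold there (1 of 16, 9; adjusted p = 5.85e-11, adjusted p = 0.147 estimated). Cxcl9, a T cell chemokine, had 1 UMI in ZyA_TNFi and was 250-fold higher (43.7 to 10006). Lcn2, Retnla and Slpi rose there by 4.63, 4.90 and 3.05 (Retnla kept in 3 of 8 fits without 1 library), as did the AT2 marker Chil1, while AT2 markers took 0.248 ± 0.122% of endothelial UMIs in ZyA_MTX and 0.112 ± 0.0604% in ZyA_TNFi.

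**Figure D5:**
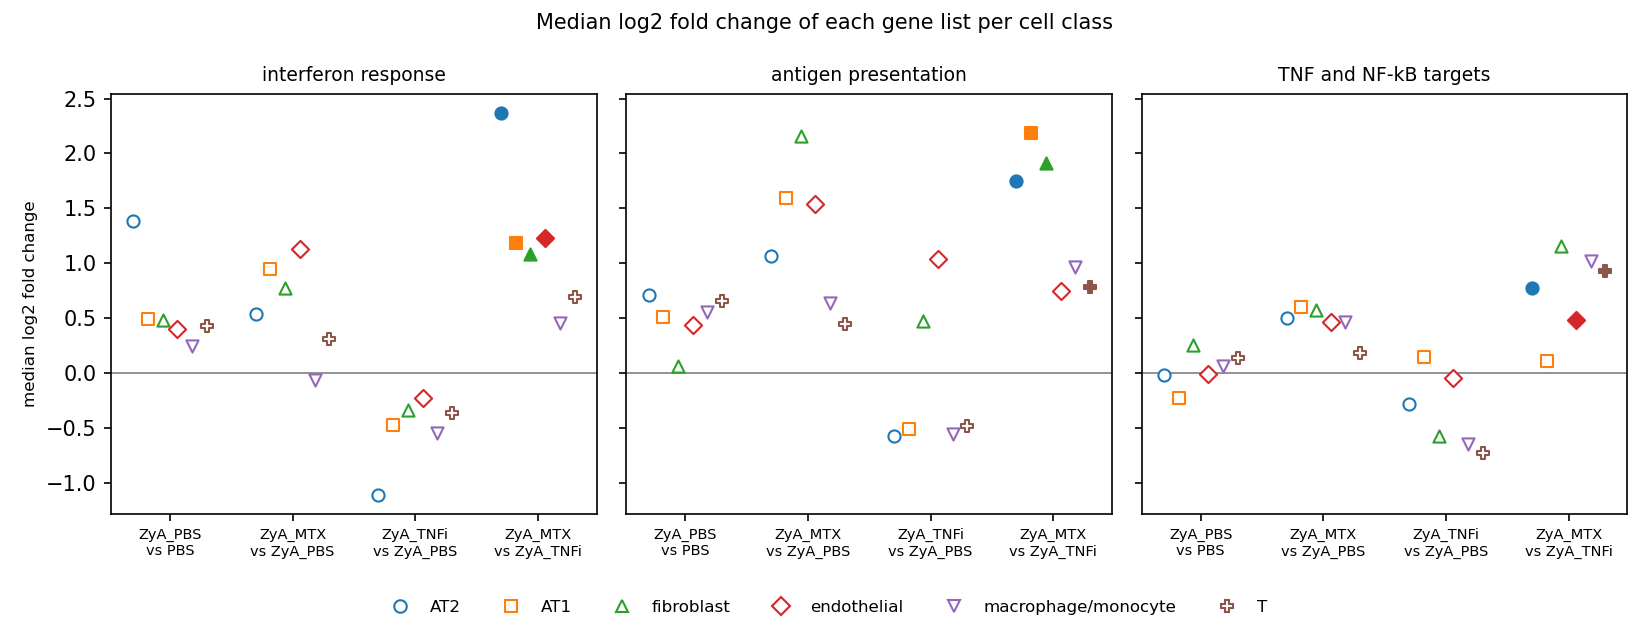
Median log2 fold change of the interferon response, antigen presentation and TNF and NF-kB target lists per class and comparison. Filled symbols pass with an estimated correlation and open symbols do not. All filled symbols belong to the drug comparison.

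In macrophage/monocyte nuclei the inflammatory cytokine gene Tnf rose from 9.20 ± 5.56 to 74.7 ± 12.8 CPM (2.89 ± 0.53, adjusted p = 0.00179). So did the mitochondrial superoxide dismutase gene Sod2 (2.52 ± 0.42, adjusted p = 0.00137) and H2-Eb1 (1.55 ± 0.29, adjusted p = 0.00235). Nr4a1 fell from 92.2 ± 10.6 to 14.3 ± 4.15 CPM (-2.60 ± 0.33, adjusted p = 9.13e-05), with Chn2 (-2.65) and Vcan, a matrix proteoglycan of monocytes (-2.94 ± 0.81, adjusted p = 0.0323). The Vcan call was kept in 5 of 16 settings and lost without any library but ZyA_MTX replicate 1 (adjusted p = 0.054 to 0.0983). Cxcl3, a neutrophil chemokine, had 1 UMI in ZyA_TNFi and was 299-fold higher (53.4 to 11815). Cluster 16, led by Nos2 and Cxcl3 among others, held 32.9% of this class in ZyA_MTX and 1.07% (6 nuclei) in ZyA_TNFi, so these calls do not tell a change within nuclei from a different mix of them. Of the markers of other classes, Pdpn, Clec9a and Lpl were higher and Calcrl, Pecam1, Cyp2f2, Siglech, Spock2 and Pi16 lower. TNF and NF-kB targets (8 of 22 rose, 14 alone; adjusted p = 4.95e-08), antigen presentation (8 of 16, 16; adjusted p = 1.92e-09) passed, as did fibrosis-associated macrophage genes (6 of 19, 9, and 1 fell alone; adjusted p = 1.83e-05) and the interferon response (5 of 29, 7; adjusted p = 0.00859). In this order they had adjusted p of 0.0902, 0.125, 0.159 and 0.744 with an estimated correlation. In T nuclei Birc3, an NF-kB target, rose (1.23 ± 0.24, adjusted p = 0.0106). TNF and NF-kB targets passed there (1 of 16, 12 alone; adjusted p = 4.75e-12, adjusted p = 0.0466 estimated). So did antigen presentation (4 of 14, 9; adjusted p = 8.77e-13, adjusted p = 0.0466 estimated). The interferon response (1 of 17, 1; adjusted p = 1.39e-05) did not hold with an estimated correlation (adjusted p = 0.288). The class II genes H2-Aa and H2-Ab1, the myeloid Fcer1g and the acute phase genes Lcn2 and Saa3 also rose in T nuclei by 2.39, 2.69, 2.88, 4.00 and 3.63. The AT2 marker Chil1 was higher, and AT2 markers took 0.222 ± 0.104% of T UMIs against 0.126 ± 0.05996%.

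The edgeR test passed 349 genes in AT2 (290 higher, 59 lower), 68 in AT1 (64 and 4), 51 in fibroblast (48 and 3), 57 in endothelial (57 and 0), 801 in macrophage/monocyte (423 and 378) and 42 in T nuclei (37 and 5). Of 63 list tests 27 passed (25 higher, 2 lower), and 12 did with an estimated correlation. The ribosomal protein share as a covariate gave 20 higher and 11 lower, and with both 0 passed. Leaving out 1 library gave 226 (ZyA_TNFi replicate 4) to 360 genes (ZyA_TNFi replicate 2) in AT2, 20 (ZyA_TNFi replicate 3) to 71 (ZyA_TNFi replicate 2) in AT1 and 9 (ZyA_TNFi replicate 3) to 44 (ZyA_MTX replicate 4) in fibroblast. It gave 8 (ZyA_TNFi replicate 1) to 72 (ZyA_TNFi replicate 2) in endothelial, 476 (ZyA_MTX replicate 2) to 668 (ZyA_MTX replicate 1) in macrophage/monocyte and 8 (ZyA_TNFi replicate 4) to 30 (ZyA_MTX replicate 3) in T nuclei. Ribosomal protein genes rose here too, 22 of 87 in AT2, 9 of 77 in AT1, 6 of 62 in fibroblast, 10 of 86 in endothelial, 8 of 85 in macrophage/monocyte and 11 of 83 in T nuclei. With the ribosomal protein share as a covariate 127, 4, 21, 1, 444 and 0 genes passed in the same order of classes. Macrophage/monocyte, T and B nuclei were more frequent in all 4 ZyA_MTX libraries than in any ZyA_TNFi library (16.3 ± 4.69 against 3.87 ± 0.669%, 13.9 ± 2.07 against 4.82 ± 1.26% and 7.03 ± 1.96 against 2.28 ± 1.498%). Each had the smallest exact permutation p possible (0.0286), but an adjusted p of 0.0667, so none passed. An edgeR test of nuclei counts passed macrophage/monocyte nuclei (log2 2.08, adjusted p = 0.0317). AT1 and endothelial nuclei had an exact p = 0.0571 (adjusted p = 0.08; 4.72 against 8.39% and 8.87 against 17.3%), and the log2 ratio of AT2 to AT1 nuclei was 2.00 ± 0.12 against 1.49 ± 0.78 (exact p = 0.286).

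On the GRCm38 build, genes the text returns to lie on chromosome 17 at 34197721 to 34201454 (Psmb8), 34187553 to 34197225 (Tap1), 34257689 to 34269419 (H2-Ab1) and 35262730 to 35267499 (H2-D1), all on the plus strand of the MHC region. Tnf lies there at 35199381 to 35202007 on the minus strand. Sftpc lies on chromosome 14 at 70520949 to 70524081 (minus) and Lcn2 on chromosome 2 at 32384633 to 32388252 (minus). How the counting treated reads of near-identical copies among MHC, Gbp and Saa genes was not tested, so single members of these families are uncertain.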

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

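All tests of explanations in this part were chosen after the results they measure had been seen. A sample was singled out where its gap to the nearest other library of its group was large against the range of that group. This rule picked 12 of 127 groups of values, and chance picks about 1 in 20.

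In AT2 nuclei of PBS, replicate 1 had 1562.6 CPM of the lipid transporter gene Abca3 (the others lay between 1351.4 and 1385.3), and replicate 2 had 588.5 CPM of the transcription factor gene Etv5 (946.28 to 975.98) and 55.867 CPM of the keratin gene Krt8 (16.189 to 18.662). The log2 ratio of AT2 to AT1 nuclei was 2.4717 in PBS replicate 4 (1.1302 to 1.2817 in the others). Nos2 stood at 46.536 CPM in AT2 nuclei of ZyA_PBS replicate 2, at 0.91032 CPM in PBS replicate 1 and at 0.41837 CPM in ZyA_TNFi replicate 4, and at 0 in all other libraries of these groups. B nuclei made up 11.63% of ZyA_PBS replicate 2 (1.0856 to 1.6245% in the others). In AT2 nuclei of ZyA_TNFi, Lcn2 stood at 29.789 CPM in replicate 1 (51.991 to 55.594 in the others) and H2-Ab1 at 49.283 CPM in replicate 3 (61.297 to 63.461). ZyA_MTX replicate 1 held 14004733 UMIs (1978486 to 3468109 in the others), with a median of 1808 per barcode (357 to 506).

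The first pattern weighed is the interferon response, higher in ZyA_MTX than in ZyA_TNFi in AT2, AT1, fibroblast and endothelial nuclei. Depth was tested as a covariate by the UMI total of the class sum, with an estimated correlation. This total is argued against as the whole cause in AT2 and AT1 nuclei, where the list held (largest adjusted p = 0.03551 by camera). The total also varies with the number of nuclei, so it does not test depth per nucleus or the calling of nuclei. In fibroblast and endothelial nuclei the list did not hold (adjusted p = 0.1077, medians 1.09 to 1.15 and 1.23 to 0.76). Depth and treatment cannot be told apart there. Nor can cytoplasmic RNA carried along with the nuclei and treatment be told apart in any of the 4 classes, since with the ribosomal protein share as a covariate the list held in none (largest adjusted p = 0.1886), although medians were 2.31, 1.07, 0.84 and 1.03 (2.37, 1.19, 1.09 and 1.23 without it) and 9, 1, 1 and 0 members still passed (of 20, 8, 2 and 7). Free RNA from other cells is not excluded either. In endothelial, AT1 and fibroblast nuclei, all tested members stood at a median of 1.417, 1.887 and 2.118 times the highest epithelial marker relative to the library (lowest library 1.071, 0.6395 and 1.268). They stood at 0.2951, 0.4933 and 0.8946 times the highest myeloid marker (Zbtb46, Csf1r and Cx3cr1). Whether the classes express these markers was not tested, so free RNA and expression cannot be told apart there. Free RNA was not tested for AT2 nuclei, and a response of the cells to the treatments stays open as a hypothesis.

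The second pattern is the rise of ribosomal protein genes in ZyA_MTX over ZyA_PBS. Within groups, the share of these genes moved together between classes (median correlation 0.905 over 15 pairs, lowest 0.756), as a shift of whole libraries in cytoplasmic RNA requires. The share was higher in every ZyA_MTX than in every ZyA_PBS library in 6 of 6 classes, which an effect of MTX within cells and a shift between library preparations both give. With no batch in the labels, these cannot be told apart.

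The third pattern is RNA outside its usual cell types in ZyA_MTX compared with ZyA_TNFi. The secreted genes Lcn2, Saa3, Slpi and Retnla in endothelial and T nuclei stood at a median of 0.817 times the highest epithelial marker or less, and MHC class II genes in T nuclei at 0.525 times. Of these genes Saa3 in T nuclei alone lay above that marker (3.43 against 2.86 for Scgb1a1), and in fibroblasts H2-Aa, H2-Ab1 and H2-Eb1 lay below it (2.12, 2.18 and 3.21 against 3.32), while Lcn2, Saa3 and Retnla lay above it there (7.73, 18.5 and 4.37) without being called. Both medians lie in the range that free RNA gives, so expression by T and endothelial cells is not shown. A candidate explanation is free RNA from other cells, with fibroblasts not excluded as a source, and no biological explanation was tested.

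Other splits of the same libraries were tested for each count of genes, 35 splits for each. In AT2 nuclei 1 of 35 splits, the real one, called as many genes in each comparison. This share is the smallest 35 splits can give and was not adjusted over the 24 counts, so chance is not excluded. The counts were 35, 43, 49 and 349 in the disease, MTX, TNFi and drug comparisons, against at most 17, 1, 8 and 2 in another split. The same holds in the MTX, TNFi and drug comparisons for AT1 (263, 189 and 68 against 82, 1 and 3) and fibroblast nuclei (197, 86 and 51 against 122, 15 and 3), and in the TNFi and drug comparisons for endothelial (621 and 57 against 75 and 21), macrophage/monocyte (44 and 801 against 8 and 0) and T nuclei (4 and 42 against 1 and 1). The counts also moved with single libraries, without which they fell to 7, 9, 0 and 226 in AT2 (ZyA_PBS replicates 2, 3 and 2, ZyA_TNFi replicate 4), 3, 34 and 20 in AT1 and 0, 2 and 9 in fibroblast nuclei (ZyA_PBS replicate 1 and, for the drug comparison, ZyA_TNFi replicate 3), 35 and 8 in endothelial (ZyA_PBS replicate 1, ZyA_TNFi replicate 1), 6 and 476 in macrophage/monocyte (ZyA_PBS replicate 2, ZyA_MTX replicate 2) and 0 and 8 in T nuclei (ZyA_TNFi replicates 2 and 4). In the disease comparison other splits called as many outside AT2 nuclei. There 3 of 35 splits called as many in AT1 (33 genes, at most 115 in another split), fibroblast (108 and 152), endothelial (62 and 128) and macrophage/monocyte nuclei (58 and 72), and 8 in T nuclei (2 and 20). In the MTX comparison 35 of 35 splits did so in macrophage/monocyte (0 and 1) and 2 of 35 in T nuclei (11 and 18). In AT1, fibroblast and endothelial nuclei the highest other split of the disease comparison exchanged PBS replicate 4 with ZyA_PBS replicate 4. The split of 115 genes in AT1 and that of 20 in T nuclei are several times the real count, which points to a structure of the samples other than their group. In endothelial nuclei of the MTX comparison the real split called the most (984), but exchanging ZyA_MTX replicate 3 with ZyA_PBS replicate 4 gave 942 and leaving out ZyA_MTX replicate 1 gave 190, so a structure of the samples other than treatment is not excluded for that count.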

How the results depend on the processing

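The alternatives chosen after the data were seen are named above, and all others were planned. A count of genes below is given where it moved by more than 1.5 times from the count in the report. The cause was not tested for any change given here, unless stated.

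With RLE size factors such counts were AT2 74, T 7 (TNFi comparison). With DESeq2 they were AT2 71, AT1 86, macrophage/monocyte 100, T 14 (disease), AT2 217, macrophage/monocyte 83, T 65 (MTX), AT2 143, fibroblast 47, endothelial 389, macrophage/monocyte 89, T 19 (TNFi). Of the named gene results, 209 kept direction and side of the threshold with RLE and 185 with DESeq2. Of the 95 list results that passed, the median changed sign with RLE in 1, the immediate early and heat shock list in endothelial nuclei of the drug comparison (to 0.027), and in 0 with DESeq2. Without a filter on low counts, more genes were tested and the counts were AT2 199, AT1 242, fibroblast 223, endothelial 272, macrophage/monocyte 293, T 59 (disease), AT2 334, macrophage/monocyte 106, T 148 (MTX), AT2 283, AT1 288, macrophage/monocyte 265, T 59 (TNFi), AT2 692, AT1 178, fibroblast 128, endothelial 187, T 237 (drug). In fits of only the 2 groups compared, which leave fewer samples to estimate the spread, they were AT2 19, fibroblast 56, macrophage/monocyte 9, T 0 (disease comparison), AT1 112, fibroblast 14, endothelial 4.0e+02 (338 higher, 66 lower), T 4 (MTX comparison), fibroblast 173, macrophage/monocyte 17 (TNFi comparison), fibroblast 110, endothelial 118, T 162 (drug comparison).

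With depth (of the class sum) as a covariate the counts were AT2 4, AT1 0, fibroblast 24, endothelial 32, macrophage/monocyte 91, T 9 (disease), AT2 3, macrophage/monocyte 2, T 28 (MTX), AT2 8, AT1 68, fibroblast 48, endothelial 104, T 16 (TNFi), endothelial 15, macrophage/monocyte 521, T 21 (drug). Of the gene lists, 22, 23, 12 and 28 passed in the disease, MTX, TNFi and drug comparisons, against 26, 25, 17 and 27 in the report. With the ribosomal protein share as a covariate the counts were fibroblast 34, T 22 (disease), AT2 0, AT1 0, fibroblast 0, endothelial 1, T 0 (MTX), AT2 16, AT1 11, fibroblast 4, endothelial 5, T 12 (TNFi), AT2 127, AT1 4, fibroblast 21, endothelial 1, macrophage/monocyte 444, T 0 (drug). The transitional alveolar state in AT1 nuclei, higher in the MTX comparison, was then lower (adjusted p = 0.018), and Retnla in endothelial nuclei went to -0.10 (adjusted p = 0.9998). With nuclei of at least 500 genes the counts were AT2 20, AT1 14, fibroblast 65, endothelial 36, T 0 (disease), AT2 22, T 3 (MTX), macrophage/monocyte 97 (TNFi), AT1 36, endothelial 9, T 19 (drug). Shares then changed sign for T (-2.96, adjusted p = 0.633) and B nuclei (-0.851, adjusted p = 0.714) in the MTX comparison and for AT2 nuclei in the drug comparison (0.286, adjusted p = 0.971). In the MTX comparison, then without ZyA_PBS replicate 4, the log2 ratio of AT2 to AT1 nuclei differed by 1.83 (exact p = 0.0286). By edgeR on nuclei counts, macrophage/monocyte nuclei passed in the drug comparison (2.08, adjusted p = 0.0317).

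The replicate numbers do not pair the libraries. Correlations between libraries of the same number ran from -0.287 to 0.189 over 93 values, of which 22 were the best of their library and 5 lay above 0.1. With the number as a block the counts were AT1 98, endothelial 108 (disease), AT2 124, macrophage/monocyte 6, T 60 (MTX), macrophage/monocyte 23, T 14 (TNFi), T 24 (drug). With the block, 191 of the named gene results and 93 of the list results kept their call.

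With an estimated correlation between genes, 0, 0, 0 and 12 lists passed in the disease, MTX, TNFi and drug comparisons. With depth as a covariate too, 1, 0, 0 and 10 passed, and with the ribosomal protein share 6, 0, 0 and 0.

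Leaving out 1 library leaves 3 in its group. Counts that moved by more than 1.5 times follow for each library left out, with the comparison in brackets. Without ZyA_PBS replicate 1 the counts were AT2 17, AT1 3, fibroblast 0, endothelial 294, macrophage/monocyte 2, T 2 (MTX), AT2 14, AT1 34, fibroblast 2, endothelial 35, T 14 (TNFi), AT1 6, fibroblast 6, T 26 (disease). Without ZyA_PBS replicate 2 the counts were AT2 7, AT1 6, macrophage/monocyte 26 (disease), AT2 121, fibroblast 342, macrophage/monocyte 170, T 300 (MTX), AT2 0, AT1 121, macrophage/monocyte 6, T 9 (TNFi). Without ZyA_PBS replicate 3 the counts were AT2 9, AT1 40 (MTX), AT1 12, fibroblast 60, T 12 (disease), AT1 97, fibroblast 40, macrophage/monocyte 87, T 16 (TNFi). Without ZyA_PBS replicate 4 the counts were AT2 22, AT1 6 (disease), AT1 286, macrophage/monocyte 114 (TNFi). Without ZyA_MTX replicate 1 the counts were AT2 16, AT1 22, fibroblast 6, endothelial 190, macrophage/monocyte 5, T 1 (MTX), AT1 34, fibroblast 32, endothelial 26, T 22 (drug). Without ZyA_MTX replicate 2 the counts were AT2 26, AT1 136, T 4 (MTX), AT1 22, endothelial 23, macrophage/monocyte 476, T 16 (drug). Without ZyA_MTX replicate 3: AT2 77, macrophage/monocyte 2, T 46 (MTX). Without ZyA_MTX replicate 4: T 25 (drug). Without ZyA_TNFi replicate 1: AT2 96, fibroblast 49, macrophage/monocyte 28 (TNFi), AT1 23, fibroblast 13, endothelial 8, T 12 (drug). Without ZyA_TNFi replicate 2: AT2 12, AT1 102, fibroblast 13, endothelial 219, macrophage/monocyte 24, T 0 (TNFi), fibroblast 29, T 12 (drug). Without ZyA_TNFi replicate 3: AT2 11, AT1 72, fibroblast 41, endothelial 274, macrophage/monocyte 24, T 0 (TNFi), AT1 20, fibroblast 9, endothelial 24, macrophage/monocyte 478, T 11 (drug). Without ZyA_TNFi replicate 4 the counts were AT2 8, AT1 103, fibroblast 53, endothelial 273 higher and 119 lower, macrophage/monocyte 26, T 0 (TNFi), AT2 226, AT1 36, fibroblast 29, endothelial 13, macrophage/monocyte 483, T 8 (drug). Without PBS replicate 1: AT2 22, AT1 6, fibroblast 14, endothelial 21, macrophage/monocyte 126 (disease). Without PBS replicate 2: AT2 14, AT1 4, fibroblast 9, endothelial 23, macrophage/monocyte 29 (disease). Without PBS replicate 3: AT1 62, T 1 (disease). Without PBS replicate 4: AT2 71, AT1 164, fibroblast 246, endothelial 150, macrophage/monocyte 36, T 0 (disease). The highest or lowest counts of results that moved less follow, with the library left out. AT2 had 360 (ZyA_TNFi replicate 2, drug). AT1 had 316 (ZyA_PBS replicate 2, MTX) and 71 (ZyA_TNFi replicate 2, drug). Fibroblasts had 103 (ZyA_PBS replicate 2, TNFi) and 44 (ZyA_MTX replicate 4, drug). Endothelial nuclei had 1138 (ZyA_PBS replicate 4, MTX), 738 (ZyA_TNFi replicate 1, TNFi) and 72 (ZyA_TNFi replicate 2, drug). Macrophage/monocyte nuclei had 668 (ZyA_MTX replicate 1, drug) and 0 (ZyA_PBS replicate 3, MTX). T nuclei had 30 (ZyA_MTX replicate 3, drug).

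List calls were lost as follows, with the camera adjusted p without the library. ZyA_PBS replicate 1: surfactant and lipid synthesis in AT2 0.0542, extracellular matrix in fibroblast 0.0517, p53 targets in macrophage/monocyte 0.0711 (disease), mitochondrially encoded in AT2 0.214, TNF and NF-kB targets in AT1 0.0691, immediate early and heat shock in AT1 0.0568, interferon response in T 0.514 (MTX), cell cycle in AT2 0.901, surfactant and lipid synthesis in AT2 0.095, immediate early and heat shock in macrophage/monocyte 0.0613, cell cycle in T 0.219 (TNFi). ZyA_PBS replicate 2: antigen presentation in AT2 0.769, interferon response in AT1 0.59, interferon response in fibroblast 0.496, interferon response in endothelial 0.113, antigen presentation in endothelial 0.195, endothelial activation in endothelial 0.0518, interferon response in macrophage/monocyte 0.24, antigen presentation in macrophage/monocyte 0.99, p53 targets in macrophage/monocyte 0.124, interferon response in T 0.769, antigen presentation in T 0.769, immediate early and heat shock in T 0.0518 (disease), mitochondrially encoded in AT2 0.057, immediate early and heat shock in AT1 0.06 (MTX), interferon response in AT2 0.229, antigen presentation in AT2 0.229, interferon response in fibroblast 0.632, TNF and NF-kB targets in fibroblast 0.228, interferon response in macrophage/monocyte 0.268, TNF and NF-kB targets in macrophage/monocyte 0.515, TNF and NF-kB targets in T 0.968 (TNFi). ZyA_PBS replicate 3: T cell activation in T 0.411 (disease), immediate early and heat shock in AT1 0.0797, interferon response in T 0.407 (MTX). ZyA_PBS replicate 4: interferon response in macrophage/monocyte 0.571 (disease), immediate early and heat shock in AT1 0.0987 (MTX), interferon response in macrophage/monocyte 0.521, immediate early and heat shock in macrophage/monocyte 0.236 (TNFi). ZyA_MTX replicate 1: immediate early and heat shock in AT1 0.339 (MTX), cell cycle in AT2 0.0646, transitional alveolar state in AT1 0.541 (drug). ZyA_MTX replicate 2: mitochondrially encoded in AT2 0.0547, interferon response in T 0.0933 (MTX), immediate early and heat shock in endothelial 0.751 (drug). ZyA_MTX replicate 3: TNF and NF-kB targets in AT1 0.0693, interferon response in T 0.0682 (MTX), immediate early and heat shock in endothelial 0.5 (drug). ZyA_MTX replicate 4: mitochondrially encoded in AT2 0.0639, interferon response in T 0.273 (MTX), interferon response in macrophage/monocyte 0.145 (drug). ZyA_TNFi replicate 1: cell cycle in AT2 0.0521, interferon response in fibroblast 0.0834, cell cycle in T 0.104 (TNFi), transitional alveolar state in AT1 0.143, immediate early and heat shock in endothelial 0.0578 (drug). ZyA_TNFi replicate 2: immediate early and heat shock in macrophage/monocyte 0.114 (TNFi), mitochondrially encoded in AT2 0.24, immediate early and heat shock in endothelial 0.285 (drug). ZyA_TNFi replicate 3: immediate early and heat shock in macrophage/monocyte 0.0756, cell cycle in T 0.103 (TNFi), immediate early and heat shock in endothelial 0.655 (drug). ZyA_TNFi replicate 4: cell cycle in T 0.0609 (TNFi), transitional alveolar state in AT1 0.123 (drug). PBS replicate 1: p53 targets in macrophage/monocyte 0.104, immediate early and heat shock in T 0.0666, T cell activation in T 0.124 (disease). PBS replicate 2: extracellular matrix in fibroblast 0.056, interferon response in macrophage/monocyte 0.0778 (disease). PBS replicate 3: immediate early and heat shock in fibroblast 0.0753, interferon response in macrophage/monocyte 0.163, interferon response in T 0.121, immediate early and heat shock in T 0.111, T cell activation in T 0.124 (disease). PBS replicate 4: antigen presentation in macrophage/monocyte 0.0506, interferon response in T 0.0502 (disease). Between 15 (without ZyA_PBS replicate 2) and 29 lists (without ZyA_PBS replicate 3) passed in the disease comparison. Nos2 in AT2 nuclei ran from -1.98 (adjusted p = 0.925, without ZyA_PBS replicate 2) to 7.85 (adjusted p = 0.0216, without PBS replicate 1) in the disease comparison, and from 1.21 (adjusted p = 0.961, without ZyA_PBS replicate 2) to -7.84 (adjusted p = 0.0436, without ZyA_TNFi replicate 4) in the TNFi comparison.

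Of the genes of the naming rule that passed, 9 of 44 in the disease, 9 of 39 in the MTX, 9 of 43 in the TNFi and 20 of 52 in the drug comparison kept their call whichever library was left out. In all 16 settings tried for them, Psmb8, Tap1, Cxcl1, H2-Ab1, Iigp1 and Gabre in AT2 nuclei, Oasl2 in AT1 nuclei and Tnf, Sod2 and Nr4a1 in macrophage/monocyte nuclei kept theirs in the drug comparison.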

Other observations

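Several cell classes and an unnamed cluster enter no comparison above. Mesothelial nuclei, from the lining of the lung, made up 3.04 ± 1.99% of nuclei in PBS, 4.90 ± 3.53% in ZyA_PBS, 0.440 ± 0.323% in ZyA_MTX and 2.79 ± 1.70% in ZyA_TNFi. Secretory airway nuclei stood at 9.96 ± 3.28%, 7.62 ± 6.74%, 2.06 ± 2.21% and 9.002 ± 2.85%. Alveolar macrophages stood at 14.99 ± 7.29%, 9.62 ± 9.70%, 6.60 ± 2.79% and 15.2 ± 8.19% in the same order, and NK nuclei at 1.33 ± 0.497%, 1.13 ± 1.66%, 3.34 ± 1.78% and 0.809 ± 0.144%. None of these was tested.

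The secretory airway shares depended on the clustering. Cluster 14, of 1313 nuclei (933 from ZyA_MTX), matched the secretory airway markers best, but had Trp63 among its top genes and was left unnamed by a rule set after the data were seen. At Leiden resolution 2.0 a cluster of 1324 nuclei (916 from ZyA_MTX) took the name secretory airway, while one of 2999 nuclei (274 from ZyA_MTX) went unnamed, and Trp63 led a cluster of 129 nuclei. Cluster 14 held 0.252 ± 0.173% of nuclei in PBS, 4.97 ± 6.67% in ZyA_PBS, 5.601 ± 4.49% in ZyA_MTX and 0.694 ± 0.732% in ZyA_TNFi. Cluster 21, of AT2-like nuclei, held 26.5% of that class in ZyA_MTX, and 94.0% of its nuclei came from ZyA_MTX replicate 1. Cluster 16, of macrophage/monocyte-like nuclei led by Nos2, Inhba, Acod1 and Cxcl3, held 32.9% of that class in ZyA_MTX, 28.9% in ZyA_PBS, 10.1% in PBS and 1.07% in ZyA_TNFi. These shares were not tested.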
